A study of Homo sapiens with 4 samples.

How the data were processed

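LS411N-5FU-R cells, a line selected for resistance to 5-fluorouracil (5-FU) from the human colon carcinoma line LS411N, were cultured for 3 days without verticillin A (0 nM, 2 arrays) or with 50 nM verticillin A (2 arrays). Per the labels' protocols, 250 ng of total RNA per sample was labelled as biotinylated cDNA and hybridised to an Affymetrix whole-transcript array. The groups were taken from the sample labels, which give 2 groups of 2 samples and no batch, scan date or other factor. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

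The authors deposited 1 log2 expression value per probe set and array, and per the submitters' processing notes GCRMA was used, a method that by default corrects background, quantile-normalizes arrays and summarises probes to probe sets. The version, the annotation, the genome build and any filter are not given in the sources used here, and no coordinates are printed. That the deposited values are on a log2 scale was read from their range, 2.60 to 14.47 over the 4 arrays, and from their medians of 4.59 and 4.62 (control) and 4.61 and 4.60 (verticillin A). The 4 arrays have nearly the same distribution of values, so a change of total RNA per cell would not show in these values. No detection calls were used here, so a low value cannot be separated from background, and a fold change of a dim gene can understate the change in RNA. The number of arrays, 2 per group, limits the precision of every value.

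The table held 53617 probe sets. The platform annotation used here names 1 gene symbol for 16098 of them and 0 have several; the remaining 37519 probe sets are unnamed here. All 16098 were matched by gene identifier to the RefSeq gene table of assembly GRCh38.p14, which supplied current symbols, gene classes and the order of genes along chromosomes. A gene with several probe sets (779 genes) was represented by the probe set with the highest mean over the 4 arrays, which left 14884 genes, 11916 of them protein-coding. Among the 73 called genes with several probe sets, 19 had probe sets whose changes differed in sign. FAS, the gene of the series title, and SETDB1 were planned as named genes, but the annotation used here gives no probe set for either, so both are not analysed here. The same holds for other genes of the lists, and 494 of their 804 genes were measured.

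Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with a constant prior) on the deposited log2 values of all 4 arrays, with treatment as the factor and no filter on low values. "Adjusted p" means limma's p after Benjamini-Hochberg adjustment over the 14884 genes, with a threshold of 0.05. A log2 change is the mean with verticillin A minus the control mean, and its standard error (SE) is the moderated one, on 2 residual and 3.43 prior degrees of freedom. Before the data were examined, 40 gene lists and the rule for named genes were fixed. The rule takes FAS, SUV39H1, SUV39H2, EHMT1, EHMT2 and SETDB1; the 10 largest rises and 10 largest falls among called genes whose 2 treated arrays lie beyond both control arrays; and, per list, up to 4 called members with the largest change, or up to 2 members given as values where none passed. A gene that several parts of the rule name counts under each. The report names members by this rule, taking a part of them for some lists.

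The 36 lists with at least 5 measured members were tested with limma's camera, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera was run again with a correlation estimated from the arrays, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, was a further alternative. Each list's median was also set against 10000 random lists of the same size matched on mean expression. Counts per list are given after adjustment over all genes and adjusted over the list alone.

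The steps were tested on simulated data. In 20 runs of the 2-against-2 comparison over 14884 genes, with 200 genes changed and the variances drawn from the fitted prior, limma recovered 20% of genes changed by 0.5, 90.4% of those changed by 1 and 99.2% of those changed by 2 on the log2 scale. Of the calls 5.23% were false and 0 had the wrong sign. Genes were drawn independently of each other. The data gave 1287 calls, more than the 200 genes changed in a run. Recovery after Benjamini-Hochberg adjustment depends on the share of changed genes, so these percentages need not hold for the data. The G2/M list, shifted by 0.25, was called in 20 of 20 runs at the preset correlation and in 0 of 20 with an estimated one. Where no list was shifted, 0 lists were called at the preset correlation. As the simulated genes were uncorrelated, these runs cannot show how often lists of correlated genes are falsely called. For the lists called in the data, the correlation estimated from the arrays lay between -0.0393 (cholesterol biosynthesis) and 0.464 (NRF2 targets). In this simulated setting, camera with an estimated correlation had low power for a shift of 0.25. In the data it called 0 lists, also where the estimated correlation lay below the preset 0.01. That was so for the G2/M (-0.0334), cholesterol (-0.0393) and fluoropyrimidine (0.000456) lists. For these a higher correlation between genes cannot be the reason for the lost call. Calls lost in this setting therefore say little for or against a list.

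The alternatives were the replicate number as a block, an intensity trend in eBayes with and without robust fitting, quantile normalization and median centring of the deposited values, leaving out the dimmest 25% or 50% of genes, averaging a gene's probe sets, testing every probe set, a minimum log2 change of 1, an adjusted p under 0.01, both other list tests, and leaving out each array in turn. Testing every probe set with an intensity trend, and testing protein-coding genes only, were added after the data had been seen.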

Results

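Transcript levels were measured on 4 whole-transcript arrays in LS411N-5FU-R, a human colon carcinoma line that had been made resistant to 5-fluorouracil (5-FU), the antimetabolite used against colorectal cancer. A pair of arrays came from control cells and a pair from cells kept for 3 days with 50 nM verticillin A, a fungal metabolite of the epipolythiodioxopiperazine class. The series concerns histone H3 lysine 9 (H3K9) trimethylation, FAS, immune escape and resistance to 5-FU, and the single comparison asks which transcripts differ in these resistant cells after verticillin A. Over all probe sets the 2 control arrays correlated at r = 0.994 and the 2 treated arrays at r = 0.995, while arrays of different groups correlated at 0.990 to 0.992. The median absolute difference between arrays was 0.118 within the control, 0.10 within the treated group and 0.141 to 0.152 between groups, on the log2 scale. These correlations are across probe sets, which are not independent replicates.

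Verticillin A raised CPA4, a secreted carboxypeptidase, 4.80-fold, from a log2 level of 5.80 ± 0.02 to 8.06 ± 0.04 (SD, n = 2 per group, adjusted p = 0.0024). GAS6-DT, a long non-coding RNA transcribed divergently from GAS6, rose 4.66-fold, and EMP1, an epithelial membrane protein, rose 3.40-fold. HMOX1, the haem oxygenase induced by oxidative stress, rose 2.77-fold (log2 change 1.47 ± 0.08, SE). The lysosomal glycoprotein CD68 rose 2.60-fold and SPP1, which encodes osteopontin, rose 2.59-fold. The other members of the 10 largest rises were KRTAP2-3, IGFBP6, LINC00640 and NAV3, which rose 2.52-fold to 2.74-fold. KRTAP2-3 has near-identical gene copies whose RNA its probes may share. The deepest fall was that of LURAP1L, which was 4.36-fold lower with verticillin A (7.98 ± 0.07 against 5.85 ± 0.01, SD, n = 2 per group, adjusted p = 0.0024). ARRDC4 and TXNIP, alpha-arrestins that restrain glucose uptake and are induced by glucose, were 4.23-fold and 4.22-fold lower. TRIB3, DDIT4 and DDIT3, all genes of the amino acid and endoplasmic reticulum (ER) stress response, were 3.99-fold, 3.54-fold and 3.49-fold lower. BEST1, a chloride channel gene, was 3.84-fold lower. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 3.25-fold lower, DMGDH, a mitochondrial enzyme of choline breakdown, 3.28-fold lower, and LRP1B, of the LDL receptor family, 2.93-fold lower.

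In all, limma called 528 genes higher and 759 lower with verticillin A out of 14884, and 3970 genes had an unadjusted p under 0.05. Changes of at least 1 on the log2 scale were few, with 24 genes higher and 56 lower. Both treated arrays lay on the same side of both control arrays in 54.8% of all genes tested, an arrangement expected by chance in 33.3%. The share of lower genes among the calls was 59.0%. It was 47.1% (750 higher, 668 lower) when the arrays were centred on their medians over these 14884 genes. Centring moved all log2 changes upward alike, that of SUV39H1 from 0.181 to 0.220. The number of calls fell when an array was left out, which also leaves 1 residual degree of freedom in place of 2. Without control replicate 1 or without control replicate 2, limma called 0 genes, with 3715 and 3528 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.0525 and 0.0502. It called 52 higher and 87 lower without verticillin A replicate 1, and 48 higher and 105 lower without verticillin A replicate 2. Whichever array was left out, the log2 changes of the middle 90% of the 1287 genes were 0.816 to 1.18 times those from all 4 arrays. These genes were called on the same 4 arrays, which favours genes with a small spread within groups. Ratios near 1 therefore follow largely from that choice and do not test the calls.

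**Figure D1:**
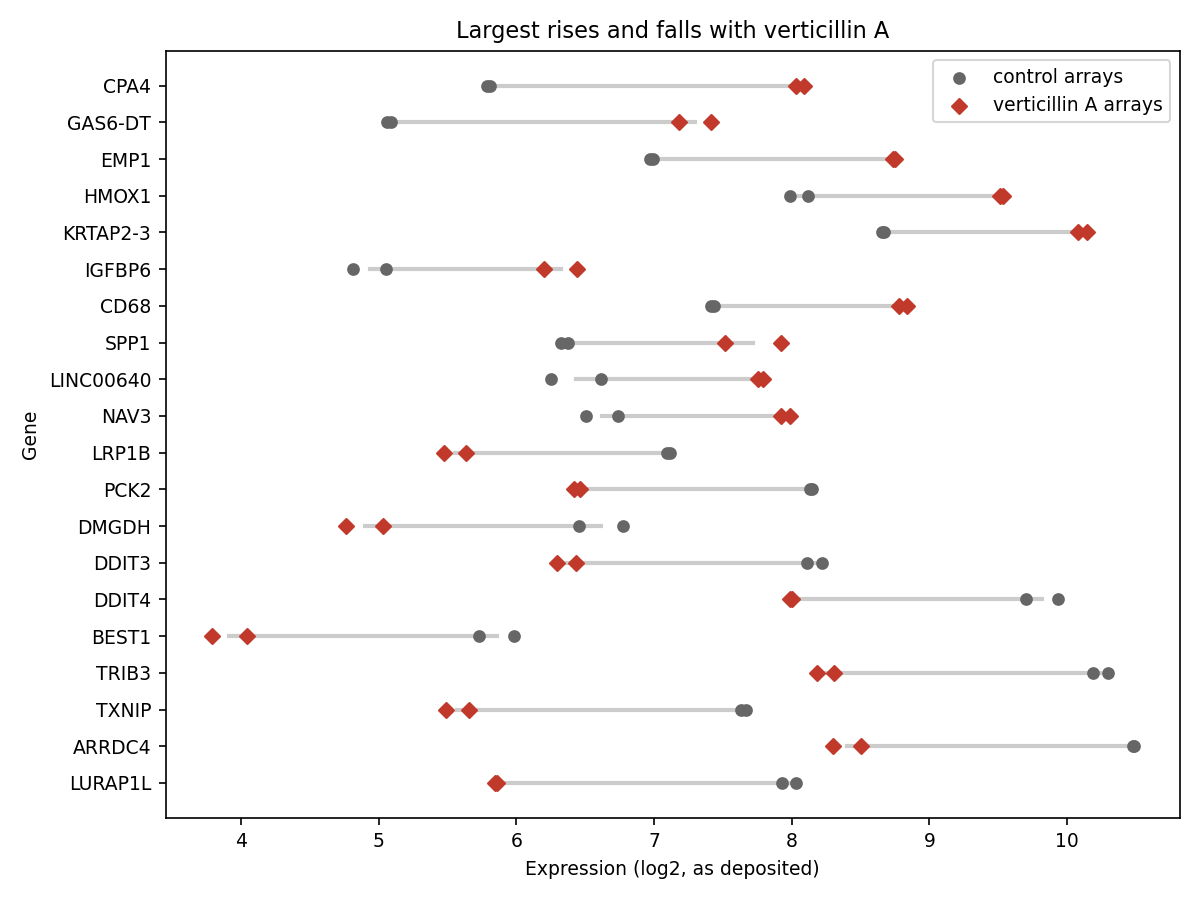
Deposited log2 expression (x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis) on each array; circles are the 2 control arrays, diamonds the 2 verticillin A arrays, and the grey line joins the group means. Genes were chosen among those whose treated arrays lie beyond both control arrays, and run from CPA4 (4.80-fold higher) at the top to LURAP1L (4.36-fold lower) at the bottom.

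Cell cycle genes were higher with verticillin A. Of 27 measured genes of G2/M and mitosis, 19 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 change of 0.40 and an adjusted p of 2.08e-15 by camera (adjusted p = 0.391 with an estimated correlation). BUB1, a kinase of the spindle checkpoint, rose by 0.80 ± 0.07 (log2 change ± SE), the mitotic kinesin KIF20A by 0.78 ± 0.07, cyclin B1 (CCNB1) by 0.69 ± 0.08 and Aurora kinase A (AURKA) by 0.68 ± 0.07. Among 20 genes of G1/S and DNA replication, 12 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 9.92e-13, adjusted p = 0.391 with an estimated correlation). They included the sliding clamp PCNA (0.87 ± 0.07), cyclin E1 (CCNE1, 0.78 ± 0.07), E2F1 (0.70 ± 0.07) and GINS2 (0.64 ± 0.07). Genes of fluoropyrimidine and folate metabolism, the pathway through which 5-FU acts, shifted up as a list of 14, of which 3 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.003, adjusted p = 0.391 with an estimated correlation). TYMS, the thymidylate synthase that a 5-FU metabolite inhibits, rose from 10.55 ± 0.05 to 11.04 ± 0.003 (SD, n = 2 per group), a 1.40-fold change with adjusted p = 0.0215. The ribonucleotide reductase subunits RRM2 and RRM1 rose 1.42-fold and 1.24-fold. With the replicate number as a block, TYMS and RRM1 lost their calls (limma adjusted p = 0.05 and 0.0903). Whether this list shifted apart from the cell cycle lists was not tested. The only measured CDK inhibitor gene, CDKN2A, fell by 0.48 ± 0.08 (adjusted p = 0.0338). Of 12 genes of double-strand break and crosslink repair, 0 rose and 1 fell, which was NBN (-0.42 ± 0.08), the same counts adjusted over the list alone, with a median of 0.02 and a camera adjusted p of 0.934. The 13 measured p53 target genes held 6 that rose and 3 that fell, the same counts adjusted over the list alone, and missed the threshold as a list (median 0.17, camera adjusted p = 0.062). BAX rose by 0.83 ± 0.13, TP53INP1 by 0.76 ± 0.07 and AEN by 0.61 ± 0.08, whereas SESN2 fell by 1.25 ± 0.08. SESN2 also belongs to the list of ATF4 and CHOP targets given below.

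Genes of the amino acid stress response moved furthest as a list. Of 13 measured targets of ATF4 and CHOP, transcription factors of the integrated stress response, 0 rose and 11 fell (0 and 13 adjusted over the list alone). Their median log2 change was -1.06, below the middle 99% of matched random lists, which ended at -0.241 (camera adjusted p = 1.11e-13, adjusted p = 0.391 with an estimated correlation). The asparagine synthetase gene ASNS was 2.67-fold lower (10.17 ± 0.06 against 8.76 ± 0.03, SD, n = 2 per group), and DDIT3, which encodes CHOP, was 3.49-fold lower. Targets of NRF2, the regulator of the oxidative stress response, were higher. Of 9 measured, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 1.81e-08), with adjusted p = 0.411 at an estimated correlation. Besides HMOX1, they included OSGIN1 (0.75 ± 0.08), the pentose phosphate enzyme TKT (0.64 ± 0.07) and peroxiredoxin 1 (PRDX1, 0.59 ± 0.08). Of 9 heat shock genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 6.23e-06, adjusted p = 0.391 with an estimated correlation). HSPA1A and HSPA1B, near-identical copies that array probes cannot reliably separate, rose 2.47-fold and 2.44-fold, and HSPH1 and BAG3 rose 1.65-fold and 1.59-fold. The 7 ER chaperone and unfolded protein response genes went both ways, with SDF2L1 higher (0.49 ± 0.08) and XBP1 (-0.74 ± 0.07), SEL1L (-0.51 ± 0.08) and HYOU1 (-0.41 ± 0.07) lower. The fall of HYOU1 lost its call when its probe sets were averaged (log2 change -0.22, adjusted p = 0.162). In this list 2 were higher and 3 lower adjusted over the list alone. Their median was 0.09, their mean -0.10 and the direction of camera down, with adjusted p = 0.868. Of 8 metallothionein genes 0 passed in limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and MT1E and MT1M had log2 changes of -0.31 ± 0.14 and 0.22 ± 0.07 (median 0.02, camera adjusted p = 0.869). Among 17 autophagy and lysosome genes, MCOLN1 rose (0.58 ± 0.10) and MAP1LC3B fell (-0.58 ± 0.09), and the list did not pass (5 higher and 2 lower adjusted over the list alone, median 0.03, camera adjusted p = 0.39).

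Metabolic lists shifted up. Of 14 cholesterol biosynthesis genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 7.41e-07, adjusted p = 0.391 with an estimated correlation). INSIG1, a sterol-regulated ER protein, rose from 8.70 ± 0.12 to 9.70 ± 0.04 (SD, n = 2 per group), the mevalonate decarboxylase MVD rose 1.90-fold, NSDHL 1.55-fold and IDI1 1.52-fold. Of 8 nuclear-encoded respiratory chain subunits, 2 rose, COX7B (0.48 ± 0.09) and COX5A (0.37 ± 0.07), and 0 fell (5 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.002, adjusted p = 0.432 with an estimated correlation). Of 10 hypoxia and glycolysis genes, 2 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.00678, adjusted p = 0.574 with an estimated correlation and 0.127 by fry). BNIP3 and LDHA rose by 0.78 ± 0.08 and 0.51 ± 0.08, whereas VEGFA, the angiogenic growth factor gene, was 2.05-fold lower. Of 15 ribosome biogenesis genes 0 passed in limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, and DDX21 and MRTO4 had log2 changes of -0.22 ± 0.07 and 0.21 ± 0.07 (median 0.05, camera adjusted p = 0.39).

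**Figure D2:**
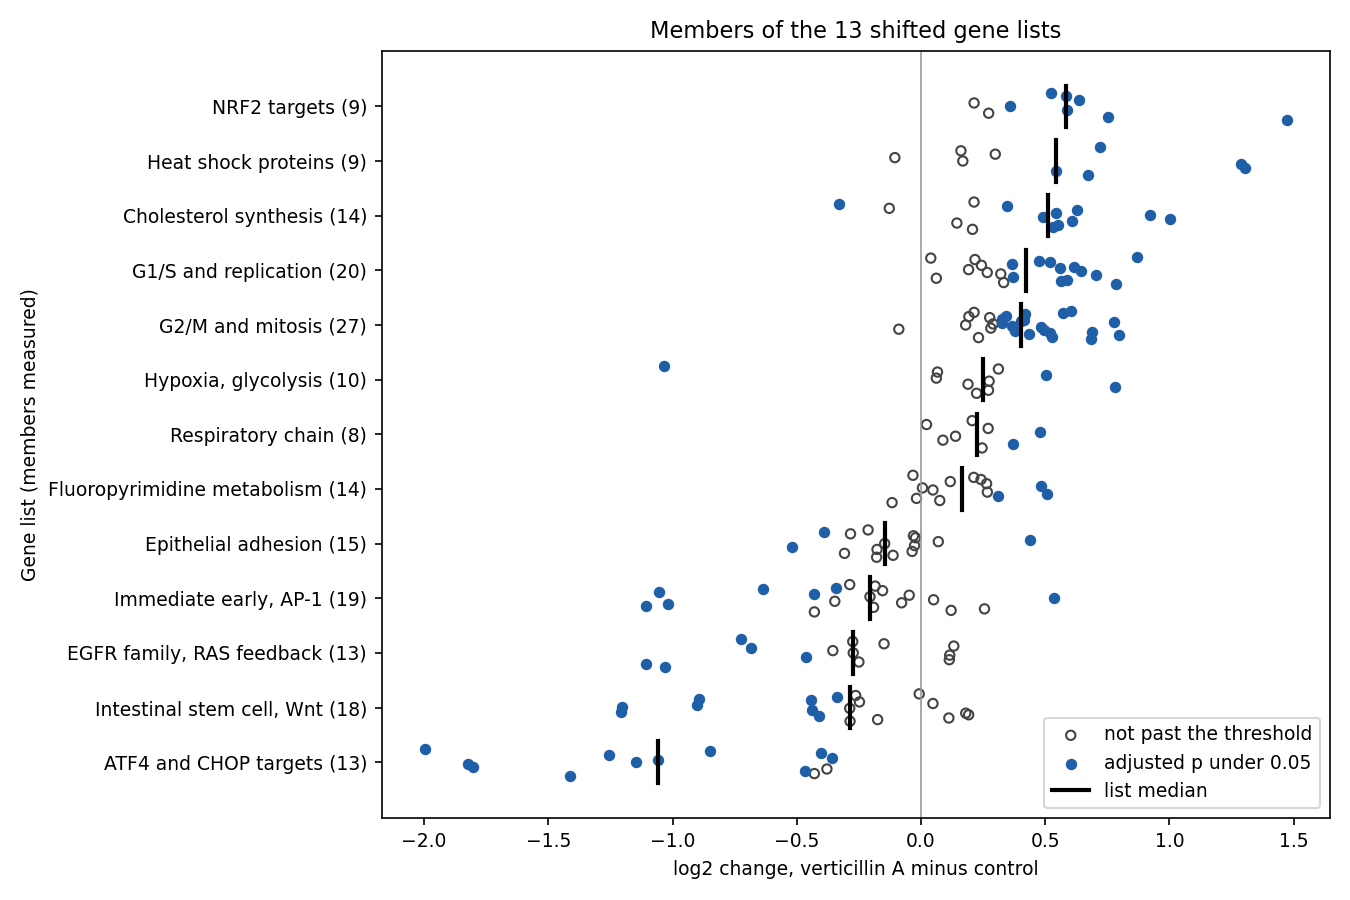
Log2 change, verticillin A minus control (x axis), of each measured member of the 13 gene lists that shifted by camera at the preset correlation (y axis, with the number of members measured); filled points passed an adjusted p under 0.05 over all genes, open points did not, and vertical bars are list medians. The ATF4 and CHOP targets lie lowest, with a median of -1.06, and the NRF2 targets highest, with a median of 0.58.

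Several stem cell and growth factor signalling genes were lower. Of 18 intestinal stem cell and Wnt target genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 1.42e-04, adjusted p = 0.402 with an estimated correlation). LGR5, the R-spondin receptor that marks crypt stem cells, was 2.31-fold lower (7.25 ± 0.14 against 6.04 ± 0.19, SD, n = 2 per group, adjusted p = 0.0113). The Wnt feedback inhibitors NKD1 and NOTUM were 2.31-fold and 1.87-fold lower, and SMOC2 was 1.86-fold lower. The other 10 genes did not pass in limma, and over the list 4 changes were positive and 14 negative. Among those not past were AXIN2 (0.11 ± 0.07) and ZNRF3 (-0.01 ± 0.08), named outside the rule after their values were seen. The fall was therefore not shared by all Wnt target genes of the list. Of 13 genes of the EGFR family, its ligands and RAS pathway feedback, 5 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 5.92e-04, adjusted p = 0.391 with an estimated correlation). They included the ligand betacellulin (BTC, -1.03 ± 0.19), and the feedback genes SPRY4 (-0.73 ± 0.09) and ETV5 (-0.68 ± 0.09). Of 19 immediate early and AP-1 genes, 6 fell and 1 rose (9 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 5.92e-04), a shift with adjusted p = 0.574 at an estimated correlation and 0.0651 by fry. DUSP6, a phosphatase of ERK that belongs to both lists, fell by 1.11 ± 0.07, JUN by 1.06 ± 0.08, EGR1 by 1.02 ± 0.08 and JUND by 0.63 ± 0.08. Epithelial adhesion genes shifted weakly, with 2 of 15 lower and 1 higher (4 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.0451, adjusted p = 0.574 with an estimated correlation). The splicing regulator ESRP1 fell by 0.52 ± 0.07 and PKP3 by 0.39 ± 0.07, and the keratin gene KRT19 rose by 0.44 ± 0.09. This list missed the threshold whichever array was left out (medians -0.20 and -0.07 and adjusted p = 0.0675 and 0.089 without control replicates 1 and 2, medians -0.17 and -0.16 and adjusted p = 0.0652 and 0.117 without verticillin A replicates 1 and 2). Of 12 mesenchymal genes, the transcription factor SNAI2 (0.82 ± 0.08) and the intermediate filament gene VIM (0.40 ± 0.07) rose and 0 fell, with no call for the list (2 higher and 1 lower adjusted over the list alone, median 0.03, camera adjusted p = 0.275). The call of VIM was lost when its probe sets were averaged (log2 change 0.16, adjusted p = 0.224). Of 18 colonic differentiation genes, the carbonic anhydrase CA2 rose 1.94-fold and VIL1, which encodes villin, was 1.54-fold lower (1 and 1 also adjusted over the list alone, median -0.03, camera adjusted p = 0.927). Of 9 neuroendocrine and neural genes, SCG2 (-0.79 ± 0.09) and NCAM1 (-0.57 ± 0.08) fell (3 lower and 0 higher adjusted over the list alone, median -0.09, camera adjusted p = 0.0981).

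Of the H3K9 methyltransferases, 4 were measured and 0 passed in limma, over all genes or adjusted over the list alone, with 1 (EHMT2) at an unadjusted p under 0.05. SUV39H1 had a log2 level of 6.34 ± 0.10 in control and 6.52 ± 0.22 in treated cells (SD, n = 2 per group, adjusted p = 0.434), and SUV39H2 9.20 ± 0.11 and 9.20 ± 0.07 (adjusted p = 0.984). EHMT1, at 7.95 ± 0.02 and 7.90 ± 0.09, had an adjusted p of 0.739. EHMT2, at 7.80 ± 0.01 and 8.02 ± 0.04, had a log2 change of 0.22 ± 0.07 and an adjusted p of 0.116, which ranged from 0.0373 with the dimmest 50% of genes left out to 0.418 without verticillin A replicate 1. FAS and SETDB1 were not analysed here. Of 11 H3K9 demethylase genes, KDM7A was 1.91-fold lower and JMJD1C 1.31-fold lower, and 0 rose (3 fell and 1 rose adjusted over the list alone, median -0.15, camera adjusted p = 0.0981). Among 16 methyltransferases of other histone residues only KMT5B, which methylates H4 lysine 20, passed (-0.53 ± 0.07, also 1 adjusted over the list alone, list median -0.03, camera adjusted p = 0.942). Among 15 genes of heterochromatin and silencing complexes only the chromatin remodeller ATRX passed (-0.45 ± 0.08, 3 higher and 2 lower adjusted over the list alone, list median 0.07, camera adjusted p = 0.528). The list of KRAB zinc finger genes, whose clusters carry H3K9 trimethylation in many cell types, did not pass. Of 47 measured, 4 rose, among them ZNF845 (0.61 ± 0.10), ZNF100 (0.52 ± 0.11) and ZNF431 (0.51 ± 0.08), and ZNF518A, a listed zinc finger gene without a KRAB domain, fell (-0.49 ± 0.07). The call of ZNF100 was lost after quantile normalization and median centring, at log2 changes of 0.54 and 0.55 (adjusted p = 0.0577 and 0.0531). Counted adjusted over the list alone, 5 were higher and 3 lower. Their median was -0.04 and the direction of camera up, with adjusted p = 0.945. Of 9 cancer-testis and germline genes 0 passed in limma, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05, and MAEL and STK31 had log2 changes of -0.19 ± 0.10 and 0.10 ± 0.10 (median 0.02, camera adjusted p = 0.964).

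Of 7 measured genes for ligands of the natural killer cell receptor NKG2D, a group singled out of the immune ligand list after its values were seen, 3 rose, 1 fell and 3 (ULBP3, RAET1E and RAET1L) did not pass. MICB rose 1.83-fold (8.41 ± 0.05 to 9.28 ± 0.03, SD, n = 2 per group, adjusted p = 0.0086), MICA 1.52-fold and ULBP2 1.98-fold, whereas ULBP1 was 2.75-fold lower (8.61 ± 0.17 against 7.14 ± 0.03, adjusted p = 0.0063). MICA and MICB are similar in sequence, so their probes may share RNA. In all, 3 of 18 tumour cell ligands of T and natural killer cell receptors rose and 2 fell (5 and 3 adjusted over the list alone, median 0.07, camera adjusted p = 0.595). Of 5 measured genes of class I antigen presentation, the peptidase ERAP1 was 1.57-fold lower (3 lower and 1 higher adjusted over the list alone, median -0.27, camera adjusted p = 0.153). Of 27 interferon-stimulated genes, IFIT1 rose (0.42 ± 0.08) and BST2, IRF9 and IFIT5 fell by 0.42 ± 0.07, 0.42 ± 0.08 and 0.36 ± 0.08, with no call for the list (1 higher and 5 lower adjusted over the list alone, median -0.02, camera adjusted p = 0.626). The call of IFIT5 was lost after quantile normalization and after median centring (log2 changes -0.33 and -0.32, adjusted p = 0.0555 and 0.0605). Of 13 NF-kB target genes and chemokines, LIF fell (-0.47 ± 0.10, 2 lower and 0 higher adjusted over the list alone, median -0.07, camera adjusted p = 0.595), a call lost after median centring (log2 change -0.43, adjusted p = 0.051). Of 21 listed genes for death receptors, their ligands and the caspase cascade, 5 were measured (BID, TRADD, APAF1, FADD and CFLAR). No death receptor, ligand or caspase gene is among them, so the list says nothing of those. In limma 0 of the 5 passed over all genes, 2 having an unadjusted p under 0.05, with 1 higher and 1 lower adjusted over the list alone. These were BID and CFLAR, with log2 changes of 0.28 ± 0.08 and -0.28 ± 0.08 (list median 0.02, camera adjusted p = 0.927). Among 10 pro-apoptotic BCL2 family genes BAX rose (0.83 ± 0.13) and BBC3, which encodes PUMA, fell (-0.38 ± 0.07, 4 higher and 1 lower adjusted over the list alone, list median 0.06, camera adjusted p = 0.39). Among 10 apoptosis inhibitors BIRC5, which encodes survivin and is also a mitotic gene, rose (0.53 ± 0.11, also 1 adjusted over the list alone, list median -0.08, camera adjusted p = 0.835). ABC drug transporters and replication-dependent histone genes, 10 and 22 genes listed, had 0 members named and were not analysed here.

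**Figure D3:**
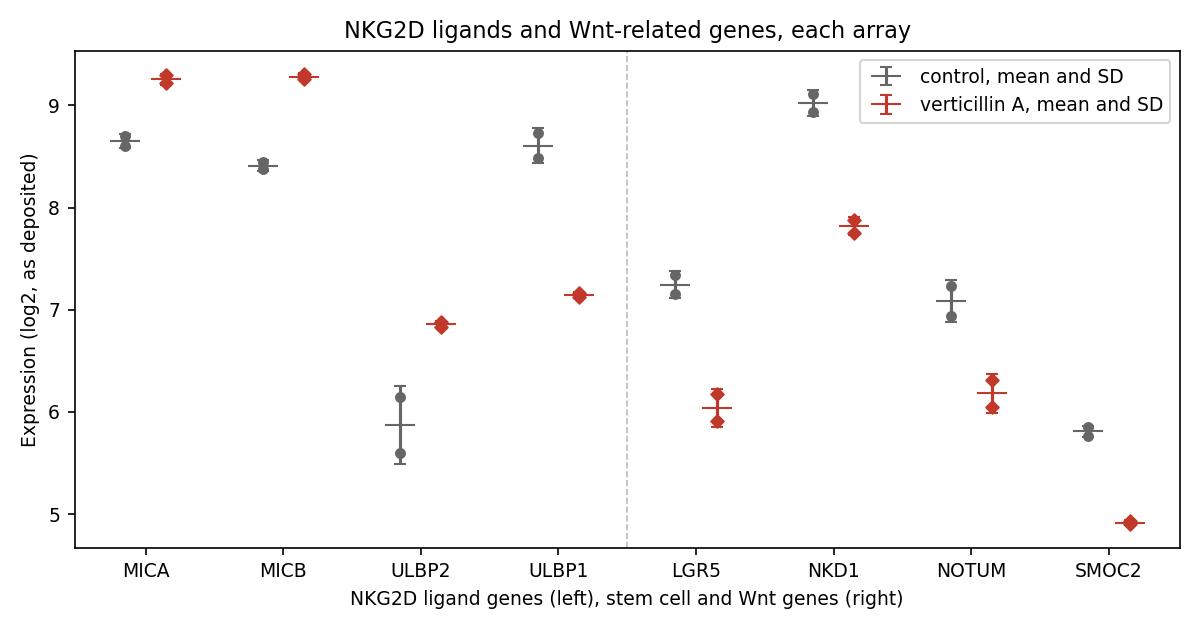
Deposited log2 expression (y axis) of 4 NKG2D ligand genes and 4 stem cell and Wnt-related genes (x axis) on each array; points are arrays, grey for control and red for verticillin A, and horizontal marks and bars are the mean and SD of the 2 arrays. MICA, MICB and ULBP2 lie higher and ULBP1, LGR5, NKD1, NOTUM and SMOC2 lower with verticillin A, ULBP1 by 2.75-fold and LGR5 by 2.31-fold.

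Leukocyte and stromal markers, which a carcinoma line should largely lack, were tested with limma too. Of 8 leukocyte markers 0 passed, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 (median -0.04, camera adjusted p = 0.835), with TYROBP at -0.24 ± 0.15 and CD8A at -0.16 ± 0.09. Of 6 fibroblast and endothelial markers 0 passed on either count, again with 0 at an unadjusted p under 0.05 (median 0.03, camera adjusted p = 0.934), with KDR at -0.19 ± 0.11 and LUM at 0.14 ± 0.09. Camera called 13 of the 36 lists at the preset correlation, 8 up and 5 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.391. All 13 calls held under quantile normalization and under median centring. The arrays already had nearly the same distribution, and centring moves all genes of an array alike. Neither setting is therefore a strong test of a comparison between genes.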

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

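This test was planned, and its repeat with an intensity trend was chosen after the first result had been seen. The report uses only probe sets with a gene name, and 37519 of the 53617 probe sets have none here. When every probe set was tested, limma called 49, and 31 of them were unnamed, 14 higher and 17 lower with verticillin A than in the control arrays. At an unadjusted p under 0.05 stood 5677 unnamed probe sets, and 832 were called once the prior followed the intensity (424 higher, 408 lower). Which transcripts they measure is not known here.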

How the results depend on the processing

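Testing every probe set with an intensity trend and testing protein-coding genes only were chosen after the data had been seen; all other settings were planned. The number of calls, 528 higher and 759 lower, became 1067 and 1361 with an intensity trend, 1054 and 1360 with a trend and robust fitting, 703 and 962 without the dimmest 25% of genes, 1070 and 1329 without the dimmest 50%, 698 and 968 for protein-coding genes only, 20 and 29 over every probe set (prior degrees of freedom 2.56), 659 and 780 over every probe set with a trend, 522 and 749 with a gene's probe sets averaged, 24 and 56 at a log2 change of at least 1, and 40 and 71 at an adjusted p under 0.01. Quantile normalization gave 678 and 731, median centring 750 and 668. The log2 minimum and the lower adjusted p are stricter by construction; for the other settings the cause was not tested. Leaving out 1 array left 1 residual degree of freedom, the lone array of its group being assumed to vary like the other group, and gave 0 to 52 higher and 0 to 105 lower. Same-numbered samples did not deviate together over genes (correlation 0.012). Whether they were grown or handled together is not given in the labels and stays open. With the replicate number as a block there were 228 and 364 calls. Among genes named by rule, 26 lost their call with this block (limma adjusted p = 0.05 to 0.0903). These were JMJD1C, ATRX, BAX, BBC3, BIRC5, TYMS, RRM1, ULBP2, BST2, IRF9, IFIT1, IFIT5 and LIF. The others were SDF2L1, HYOU1, LDHA, CDKN2A, NBN, COX7B, COX5A, VIM, KRT19, PKP3, ZNF845, ZNF100 and ZNF431. Of 100 called genes among those named by rule, 98 kept the call under quantile normalization, 97 under median centring, 98 with probe sets averaged, 74 with the block, 15 over every probe set, and 0, 0, 43 and 44 without control replicates 1 and 2 and verticillin A replicates 1 and 2. The 8 lists up and 5 down were 8 and 3 by fry, 0 and 0 with an estimated correlation, 8 and 7 over every probe set and 8 and 4 whichever array was left out. Fry lost the immediate early, hypoxia and epithelial adhesion lists and gained the mesenchymal list (adjusted p = 0.0412); testing every probe set gained the H3K9 demethylase and neuroendocrine lists (both 0.0493). The epithelial adhesion list was also lost without the dimmest 25% and 50% of genes and for protein-coding genes only (0.0773, 0.0956 and 0.0522). The count of H3K9 methyltransferases past the threshold, 0, was 1 without the dimmest 50% of genes. Uncalled changes that turned sign were SUV39H1 with probe sets averaged (-0.0219), SUV39H2, which lay between -0.0719 and 0.0817 with 1 array left out (-0.0719 without control replicate 1, -0.0466 without verticillin A replicate 2), and EHMT1, which lay between -0.117 and 0.0127 (0.0127 without verticillin A replicate 1). FAS gave no value under any setting. No detection calls were used, so which dim genes lie at background is open.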

Other observations

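Of the tests in this part, only the one that leaves out arrays for the G2/M list was written down before its result had been seen; all others, and the genes named in the next paragraph, were chosen afterwards.

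DKK1 and FRZB, singled out among the called genes with no list of Wnt antagonists tested, were higher with verticillin A. DKK1, a secreted inhibitor of the Wnt co-receptors LRP5 and LRP6, rose 2.13-fold (9.92 ± 0.005 to 11.01 ± 0.001, SD, n = 2 per group, adjusted p = 0.005), and FRZB, a secreted frizzled-related protein, rose 2.29-fold (5.46 ± 0.16 to 6.66 ± 0.37, adjusted p = 0.0259). NOTUM, a secreted Wnt inhibitor too, was 1.87-fold lower. GAS6, the ligand of the AXL receptor kinases, rose 2.31-fold beside its divergent transcript GAS6-DT (adjusted p = 0.0064). Among microRNA genes, the clustered MIR221 and MIR222 rose 1.47-fold and 1.36-fold, and MIR21 was 1.60-fold lower (adjusted p = 0.0233, 0.0249 and 0.016). Whole-transcript probes for these genes can also read their precursor transcripts. All of these calls rest on 2 arrays per group, as do those of the report.

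By camera at the preset correlation, the cell cycle lists shifted up and the ATF4 list down after verticillin A. These calls were lost by camera with an estimated correlation (adjusted p = 0.391 for each). That correlation was -0.0334 for the G2/M list, 0.162 for the G1/S list and 0.168 for the ATF4 list. A correlation above the preset 0.01 therefore does not account for the lost call of the G2/M list. A single array does not account for the shift of the G2/M list. Its median change lay between 0.3505 and 0.4038 with any 1 array left out, where under 0.2 had been set as the bound. The median of the ATF4 list, -1.059, lay below the -0.241 at which the middle 99% of matched random lists ended. The arrays already had nearly the same distribution of values, and this list was picked for having moved furthest. The comparison is therefore not a strong test of a shift of brightness that moves all genes of a level. Denser or more depleted control cultures after 3 days may give the same pair of changes. Hypoxia and glycolysis genes, which would be higher in hypoxic controls, had a median of 0.2479, with 9 of 10 changes positive and VEGFA at -1.034. The glucose-induced ARRDC4 and TXNIP were higher in the controls, where glucose depletion alone would lower them. Both were picked from the largest falls, and the compound may itself move any of these genes, so the values do not decide. Depletion of amino acids in the controls was not tested. Denser or more depleted controls and an effect of the compound itself cannot be told apart here.

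CD68 and SPP1, which macrophages express strongly, were among the largest rises. RNA from macrophages in the treated cultures would bring other macrophage transcripts with it. The 5 macrophage genes of the leukocyte list fixed beforehand (LYZ, TYROBP, CD14, CSF1R and CD163) had a median log2 change of -0.0414, and the highest upper bound of their 95% confidence intervals was 0.272. LYZ, an abundant macrophage transcript, stood at 4.58 ± 0.02 in control and 4.63 ± 0.09 in treated cells (SD, n = 2 per group). Added macrophage RNA would show most in genes that the control cells hardly express, so these changes argue against that source, and a response of the carcinoma cells is left as a hypothesis, found and tested on the same data.

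The snaR genes, a family of small non-coding RNAs made by RNA polymerase III, rose in 5 of 8 cases: SNAR-H by 1.33 ± 0.09 (log2 change ± SE), SNAR-B1 by 0.87 ± 0.08, SNAR-D by 0.82 ± 0.15, SNAR-C1 by 0.76 ± 0.08 and SNAR-G2 by 0.41 ± 0.07. Better recovery of small RNAs from the treated cultures would raise other small structured RNAs too. The 23 small Cajal body RNAs had a median change of -0.0481 (bootstrap interval over genes -0.0845 to 0.00623). Of them 3 rose and 0 fell, against 528 higher and 759 lower among all 14884 genes. The interval holds no spread between cultures, so it speaks only of these arrays. As the copies are near-identical, RNA of 1 copy may stand behind several probe sets. The changes of the 8 genes spanned 1.24, more than 0.297, a doubled standard error of a difference, but probe sets that share only some probes would differ too, so this stays open.

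If inhibition of H3K9 methylation released silenced genes broadly, rises should be over-represented among the dimmest genes. Of the 3720 genes in the dimmest 25%, 7 rose and 12 fell, against 521 that rose and 747 that fell among the others, an odds ratio of 0.836 (95% confidence interval 0.277 to 2.32, Fisher's exact test, two-sided p = 0.817). The interval holds both no difference and a doubling of the odds, so the calls among dim genes are too few to decide. The dimmest genes were also chosen by their mean over control and treated arrays together. A silenced gene that is released raises this mean and can leave the dim set. For this reason too the test cannot decide whether silenced genes were released. The KRAB zinc finger and cancer-testis lists of the report, with medians of -0.04 and 0.02, did not pass either.

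A last hypothesis was that neighbouring genes share a change. Neighbours were taken as consecutive measured protein-coding genes on a chromosome, so genes not measured here may lie between them. Over 11892 such pairs, the log2 changes had a rank correlation of 0.0516, and 0.0495 without pairs that share a name stem. The first value lay above the highest of 10000 random gene orders, 0.0349 (permutation p = 1e-04, the smallest these orders can give). These correlations are across genes, which are not independent replicates. The difference between the 2 control arrays gave 0.0337 between neighbours and that between the 2 treated arrays 0.0103, so a part of the value may be technical, and whether 0.0516 exceeds 0.0337 was not tested. The relation is weak in size.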
